A study of Mus musculus with 6 samples.

How the data were processed

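RNA from inguinal white adipose tissue of diet-induced obese wild-type mice was sequenced in 6 libraries, 3 from mice given recombinant Adissp and 3 from controls. Per the labels, total RNA was isolated with TRIzol, ribosomal RNA was depleted with the KAPA RNA HyperPrep Kit with RiboErase, and the libraries, described as biological triplicates, were sequenced on a NovaSeq X. The labels put all 6 libraries in batch 1, and they do not state what the controls received, the age or the sex of the mice. Per the submitters' processing notes, the authors aligned reads with STAR and counted them per gene with featureCounts on mm39 (GRCm39). Versions, the annotation release, the strand setting, the read length and whether reads or fragments were counted are not given in the sources used here. The deposited count table holds whole, unnormalised counts for 57180 genes. The deposited FPKM and TPM tables hold 23524 genes, which are those with at least 10 counts over the 6 libraries. The largest total of a gene they leave out was 9 counts. The deposited FPKM values equal the counts divided by a fixed gene length and by the total over the listed genes, with a largest relative difference of 6.7e-15. The deposited TPM values of each library sum to 1e+06 over the same genes. All columns were matched to a library by their headers, with 0 unmapped. Gene symbols, identifiers and positions are those of the deposited tables. The reference annotation at hand was of another build and was not used. FPKM values entered no test, and TPM values entered only alternatives.

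The comparison, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except those said below to be added. Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with the group and default settings left 17320 genes, libraries were scaled with TMM factors, and the quasi-likelihood test (robust, ADISSP minus Control, 3 against 3, no covariate) was run. TMM factors were 1.16, 1.18 and 1.05 in Control and 0.88, 0.88 and 0.90 in ADISSP. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed, and only those are said to have risen or fallen. The standard error of a log2 fold change is its size divided by the square root of the test's F. CPM (counts per 1e+06) take each library's total times its TMM factor as the denominator, with SD over 3 libraries. Where a group had no count, the fold is a lower bound against a floor of 3 counts over the group, which is 0.0840 CPM in ADISSP and 0.0595 CPM in Control. For this bound the other group's summed counts are divided by its summed scaled totals, which differs slightly from its mean CPM. With 1 to 3 counts in a group, the ratio of summed counts has a 95% exact (conditional binomial) interval. The labels mention no molecular identifiers, so intervals and floors cover counting error only. Total counts of 10357930 to 15658428 per library put 1 library's floor of 3 counts at 0.192 to 0.290 CPM.

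Gene lists were 39 sets of processes and cell type markers, of which 38 had at least 5 tested genes. They were compared with limma 3.58.1's camera on log CPM (prior count 2) with a preset inter-gene correlation of 0.01, and Benjamini-Hochberg adjustment over the 38 lists. This put 17 lists higher and 11 lower in ADISSP. With a correlation estimated per list none passed, and the smallest adjusted p was 0.441 (7872 single genes had an unadjusted p under 0.05 in edgeR). By fry, which tests whether a list's genes move on balance one way or, in its mixed form, in either direction, and which compares them with no other genes, 28 lists had an adjusted p under 0.05 one way. These were not the same lists as camera's. Fry also called the adipokine and endoplasmic reticulum stress lists, and it left out the T cell and skeletal muscle lists (unadjusted fry p 0.0606 and 0.0459). Cell type markers in mixed tissue follow the share of a cell type as well as its state. Genes named in the text are 15 fixed ones: Adissp, Ucp1, Cidea, Ppargc1a, Dio2, Adipoq, Lep, Pparg, Slc2a4, Fasn, Pnpla2, Adgre1, Tnf, Ccl2 and Col1a1. Added to them are changed genes with non-overlapping groups, a mean of at least 1 CPM and a symbol that is not a predicted-gene name: the 8 with the largest and the 8 with the smallest log2 fold change and the 6 with the smallest p. For each list described, the 3 members with the smallest p are named. The sets of depot, Hox, fibre and lymph node stroma genes in the closing part were written after the main results were seen. Genes named outside this rule are said to have been named after their values were seen. Paralogues such as class II and ribosomal protein genes can share reads, and genes overlapping on opposite strands cannot be told apart without the strand setting, so their values are uncertain.

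The test was tried on simulated counts for 17320 genes with the real means and library sizes and 200 genes changed, 10 times. With dispersions of single genes, 47.7% of genes changed by a log2 fold of 1 and 83.2% of those changed by 2 were found, 100% with the right sign. The share of false calls was 11.3% on average (4.26% to 16.1%), above the nominal 5%. With dispersions on the trend the shares found were 48.7% and 90.1%, and false calls made up 5.27% (2.08% to 8.64%). The data called 6058 genes changed, and the simulation held no differences in tissue makeup between libraries. These shares of false calls therefore need not hold for the real calls. Of 300 unchanged gene lists 0 were called by camera, and 4.57% and 4.81% of unchanged genes had an unadjusted p under 0.05 in the respective noise models. Genes were simulated independently of each other, so the count of lists cannot show how camera behaves when list members are correlated. In the data the estimated correlation was 0.34 for thermogenic genes and 0.87 for the tricarboxylic acid cycle.

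Alternatives were RLE and upper-quartile factors, no filter and a stricter filter (1 CPM in 3 libraries and a mean of 50 counts), the replicate number as a block, and each library left out in turn. Others were DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), log2(TPM + 0.1) and unfiltered log2(TPM + 1), a minimum log2 fold of 1, an estimated correlation, and lists without shared members. Added after seeing the data were Control 3 as the only control, a muscle score and a B cell score as covariates, and library totals without factors. With Control 3 as the only control the spread comes from the 3 ADISSP libraries alone. The B cell score did not overlap between the groups, so a fit with it rests on extrapolation between them. Values on log2(TPM + 1) understate the change of low genes. No 2 libraries were copies of each other: chi-square per gene between libraries of 1 group was 9.35 to 59.3. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Raw reads were not used here.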

Results

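Inguinal white adipose tissue, a fat depot under the skin, was profiled by RNA sequencing in 6 libraries from wild-type mice made obese on a high-fat diet. The mice behind 3 libraries had received recombinant Adissp, 68 nmol/kg each day over 33 days (ADISSP), and 3 libraries came from controls (Control). Adissp, adipose secreted signalling protein, is a protein that fat cells release. The comparison asks what the treatment changed in the RNA of this depot, within a series on Adissp as a possible agent against diabetes and cardiometabolic disease. Total counts were 15228295, 15400072 and 13966685 in Control 1, 2 and 3 and 14336110, 10357930 and 15658428 in ADISSP 1, 2 and 3. Of the 57180 genes listed, 32254 had a count in any library and 17320 had enough counts to be tested. Transcripts of the mitochondrial genome held 4.2%, 3.13% and 3.58% of the counts in the Control libraries and 9.22%, 11.1% and 8.43% in the ADISSP libraries. The 10 most abundant genes of each library held 10.4%, 9.54% and 11% of the Control counts and 15.8%, 17.5% and 15.3% of the ADISSP counts.

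Adissp-treated fat had a different transcriptome: mitochondrial and brown fat genes rose, and many genes of lymphocytes, macrophages and connective tissue fell. Changes are log2 fold changes of ADISSP over Control, levels are mean CPM ± SD with n = 3 per group, and adjusted p values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 17320 genes, 6058 (35.0%) changed at an adjusted p under 0.05, with 3197 higher in ADISSP (2815 protein-coding) and 2861 lower (2407 protein-coding). Of these, 1324 rose and 1406 fell at least 2-fold. In 8626 genes (49.8%) the CPM of the groups did not overlap, where chance alone gives 10%. The first principal component held 72.0% of the variance and put Control 1 and 2 at -81.0 and -85.9, Control 3 at -15.3 and the ADISSP libraries at 57.5 to 66.0. Control 3 also stood apart on the second component (12.5%), at -59.0. Its mean log2 CPM of B cell genes was 4.46, against 6.24 and 6.44 in Control 1 and 2 and 1.41 to 2.11 in ADISSP. Its skeletal muscle genes stood at 7.46, against 1.62 and 2.07 in Control 1 and 2 and 7.32 to 7.40 in ADISSP. Because of these differences, counts are also given against Control 3 alone, a comparison chosen after seeing the data, in which 3190 genes passed. With 1 control library its spread comes from the ADISSP libraries alone, so calls against Control 3 take no account of differences between control mice. Genes that passed both there and with all 6 libraries kept their direction. The fits share Control 3 and the ADISSP libraries, so this is not separate support. Without Control 3 the count of changed genes rose to 8517, and without Control 1 it fell to 3823, with 1563 lower. The genes lower in ADISSP numbered 1706 without Control 2, and 1672, 1849 and 1772 without ADISSP 1, 2 and 3.

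The heat-producing programme of brown and beige fat cells rose strongly in ADISSP. It covered the uncoupling protein itself, its transcriptional coactivator, the enzyme that activates thyroid hormone locally, and fuel-handling genes. The Adissp gene also rose, from 43.5 ± 8.79 to 128 ± 6.23 CPM (log2 fold change 1.56, SE 0.14, adjusted p = 8.3e-05). Ucp1, which uncouples respiration from ATP synthesis, went from 66.1 ± 26.4 to 3075 ± 269 CPM (log2 fold change 5.54, SE 0.32, adjusted p = 2.5e-05). The lipid-droplet gene Cidea went from 26.8 ± 8.82 to 615 ± 39.9 CPM (log2 fold change 4.52, SE 0.24, adjusted p = 1.3e-05). The coactivator Ppargc1a went from 9.96 ± 1.14 to 85.0 ± 5.30 CPM (log2 fold change 3.09, SE 0.12, adjusted p = 1.6e-06), and the deiodinase Dio2 from 11.6 ± 4.72 to 145 ± 11.5 CPM (log2 fold change 3.64, SE 0.29, adjusted p = 2.5e-04). Their identifiers and GRCm39 positions are ENSMUSG00000027327, chromosome 2, 130988244 to 131002001 (Adissp), ENSMUSG00000031710, chromosome 8, 84016981 to 84025081 (Ucp1), ENSMUSG00000024526, chromosome 18, 67476674 to 67500855 (Cidea), ENSMUSG00000029167, chromosome 5, 51611592 to 51725068 (Ppargc1a) and ENSMUSG00000007682, chromosome 12, 90691326 to 90705812 (Dio2). Of 24 thermogenic genes tested, 20 rose and 3 fell, the same numbers when adjusted over the list alone, with a median of 3.58. Acot11 rose by 4.77 and Letmd1 by 3.52. The 3 that fell, chosen here after their values were seen, were Tbx1 (-3.07), Tmem26 (-2.70) and Tnfrsf9 (-1.63), which are used as markers of beige fat cells. In Control 1, 2 and 3 Tmem26 stood at 3.06, 3.75 and 0.889 CPM and Tnfrsf9 at 1.87, 2.42 and 0.957 CPM, lowest in Control 3 as lymphocyte genes were. With the B cell score as a covariate, a score that did not overlap between the groups, they were 1.41 and 1.24, neither past the threshold. Of these, Tnfrsf9 lost its call without any 1 library other than Control 3, with adjusted p from 0.0715 without ADISSP 2 to 0.147 without Control 2. By camera, the gene list test used throughout, the adjusted p was 3.6e-11, and adjusted p = 0.441 with an estimated correlation. Against Control 3 alone 20 were higher and 1 lower past the threshold, by the spread of the ADISSP libraries alone, with a median of 3.28, and Tmem26 and Tnfrsf9 were no longer past the threshold. The separate list of 10 creatine and calcium cycling genes had a median of 0.48 and a camera adjusted p of 0.0254 (adjusted p = 0.482 with an estimated correlation). In it Alpl, Atp2a2 and Ckb rose by 2.87, 0.91 and 0.87 and Gatm fell by 0.92, also when adjusted over the list alone, with Gatm named after its value was seen. This list's median was 0.26 without Control 1 and 0.94 without Control 3, and it lost its call without Control 2 (adjusted p = 0.0559, median 0.18). With only Control 3 its median was -0.05, and its mean log2 CPM was 3.36, 3.49 and 5.72 in Control 1, 2 and 3 and 5.72 to 5.78 in ADISSP, so that Control 3 stood with ADISSP as it did for skeletal muscle.

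**Figure D1:**
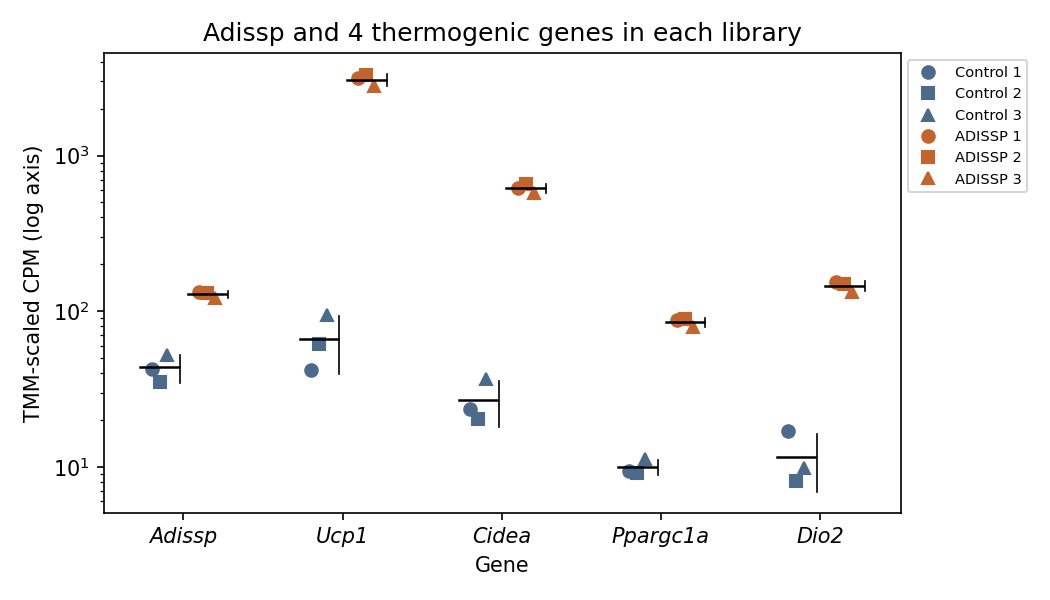
Each point is 1 library's TMM-scaled CPM (log axis) of Adissp, Ucp1, Cidea, Ppargc1a and Dio2, with the mean as a line and the SD as a bar (n = 3 per group). All ADISSP libraries lie above all Control libraries in the 5 genes, and mean Ucp1 went from 66.1 to 3075 CPM.

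Genes of mitochondrial respiration and fuel oxidation rose together. The rise took in respiratory chain subunits from the nucleus and from the mitochondrial genome, the tricarboxylic acid cycle, fatty acid oxidation, branched-chain amino acid breakdown and glycolysis. Of 74 nuclear-encoded respiratory chain subunits, 73 rose and 0 fell, with a median of 1.82. Cox7b rose by 2.17, Cox5a by 2.34 and Cox5b by 2.17. All 73 were also higher when adjusted over the list alone. Of 12 mitochondrially encoded mRNAs, 10 rose (11 adjusted over the list alone) and 0 fell, with a median of 1.68. Among them mt-Co2 rose by 2.18, mt-Nd5 by 1.93 and mt-Nd6 by 1.98. In the tricarboxylic acid cycle 17 of 18 genes rose, with the same number adjusted over the list alone and a median of 2.06, led by Sucla2 (2.61), Idh3g (2.47) and Idh3b (2.44). In fatty acid oxidation 21 of 23 rose, with a median of 1.82, including Acaa2 (3.21), Slc25a20 (2.37) and Etfdh (2.41). The 1 that fell, named after its value was seen, was Cpt1a (-0.73), and both numbers held when adjusted over the list alone. In branched-chain amino acid breakdown 17 of 19 rose (18 adjusted over the list alone), with a median of 0.98, among them Bckdha (1.95), Pcca (1.33) and Acat1 (1.52). In glycolysis 13 of 15 rose, the same adjusted over the list alone, with a median of 1.42, among them Ldhb (3.27), Pgam1 (2.02) and Pfkl (2.06). Camera's adjusted p was 3.7e-35 for nuclear respiratory chain subunits, 3.3e-06 for the mitochondrial genome, 9.3e-14 for the tricarboxylic acid cycle, 2.1e-13 for fatty acid oxidation, 1.0e-09 for amino acid breakdown and 5.8e-07 for glycolysis. Each of these 6 lists had adjusted p = 0.441 with an estimated correlation. With Control 3 as the only control, 71 respiratory chain subunits, 9 mitochondrially encoded mRNAs, 17 tricarboxylic acid cycle, 20 fatty acid oxidation, 18 amino acid breakdown and 11 glycolysis genes were higher past the threshold, by the spread of the ADISSP libraries alone, and 1 fatty acid oxidation gene (Cpt1a) and 1 glycolysis gene (Pfkm, -0.68, named after its value was seen) were lower. Pfkm was 0.71 and not past the threshold with all libraries, but 3.06 and past it without Control 3.

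Fat cell metabolism also moved, mostly upward: many genes that make, store and release fat and many fat cell identity genes rose. Of 18 genes of fatty acid synthesis, 11 rose and 0 fell, or 12 and 1 adjusted over the list alone, with a median of 0.96. The fatty acid synthase Fasn went from 3457 ± 561 to 12505 ± 2015 CPM (log2 fold change 1.85, SE 0.18, adjusted p = 1.2e-04). Elovl6 rose by 3.48, Thrsp by 2.86 and Acly by 2.06. Of 16 genes of triglyceride synthesis and fatty acid uptake, 11 rose and 2 fell, also adjusted over the list alone, with a median of 0.77. They included Agpat3 (1.71), Gpam (2.0) and Gpd1 (2.19). The 2 that fell, named after their values were seen, act in fatty acid uptake: Gpihbp1 (-0.43) and Cd36 (-0.43). Their calls were lost for Gpihbp1 without ADISSP 1 or 3 (adjusted p up to 0.0722), and Cd36 without Control 1 or ADISSP 1, 2 or 3 (adjusted p up to 0.151). Of 17 lipolysis genes 8 rose and 1 fell, or 12 and 1 adjusted over the list alone, with a median of 0.38 that was -0.18 on log2(TPM + 1). The lipase gene Pnpla2 rose by 1.35 (SE 0.15, adjusted p = 2.3e-04), Adrb1 by 2.68 and Adcy3 by 1.69. Of 16 fat cell identity genes 10 rose (12 adjusted over the list alone) and 0 fell, with a median of 0.57 that turned just below 0 on log2(TPM + 1). Pck1 rose by 2.07 and Cebpb by 2.12. Pparg, the master regulator of fat cells, went from 175 ± 27.3 to 275 ± 11.4 CPM (log2 fold change 0.66, SE 0.13, adjusted p = 0.00497), but on log2(TPM + 1) its value was 0.09 and did not pass. The adjusted p of camera was 1.4e-04 for fatty acid synthesis, 4.7e-04 for triglyceride synthesis, 2.3e-04 for lipolysis and 9.1e-05 for fat cell identity. These lists had adjusted p = 0.441 with an estimated correlation, except triglyceride synthesis (adjusted p = 0.445). Against Control 3 alone 9, 8, 7 and 7 genes of these lists were higher and 0, 2, 1 and 0 lower past the threshold, in the same order.

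Some genes of glucose uptake and insulin signalling rose, and the fat hormones adiponectin and leptin did not pass the threshold. The insulin-responsive glucose transporter Slc2a4 went from 136 ± 29.5 to 316 ± 19.9 CPM (log2 fold change 1.21, SE 0.16, adjusted p = 6.2e-04). Of 18 genes of this list 9 rose and 1 fell, or 9 and 2 adjusted over the list alone. They included Pdk4 (3.13) and Hk2 (1.39), and the 1 that fell, named after its value was seen, was Igf1 (-0.72). The median of 0.34 turned just below 0 on library totals and was -0.23 on log2(TPM + 1). Camera gave an adjusted p of 0.0195, with adjusted p = 0.441 with an estimated correlation. Against Control 3 alone the list did not pass in camera (adjusted p = 0.0697), with 5 genes higher and 1 lower (Igf1). Adipoq went from 1405 ± 271 to 1789 ± 126 CPM (log2 fold change 0.35, SE 0.15, adjusted p = 0.112), a change that did not pass. It passed without Control 3 (0.52, adjusted p = 0.00309) and was -0.22 on log2(TPM + 1). Lep went from 2292 ± 324 to 1749.9 ± 495 CPM (log2 fold change -0.39, SE 0.21, adjusted p = 0.177), and passed only without ADISSP 3 (-0.62, adjusted p = 0.0456) among the fits with 1 library left out. Of 24 adipokine genes 7 rose and 2 fell, the same adjusted over the list alone, with a median of 0.20 and a camera adjusted p of 0.220, or 0.0415 and past the threshold with no filter on low counts. Nampt rose by 1.63 and Vegfa by 1.34, while Slit2 (-1.25) and Rarres2 (-0.38), named after their values were seen, fell. Rarres2 lost its call without Control 1 or ADISSP 1, 2 or 3 (adjusted p up to 0.126). The adipokine median was -0.15 on library totals and -0.37 on log2(TPM + 1).

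**Figure D2:**
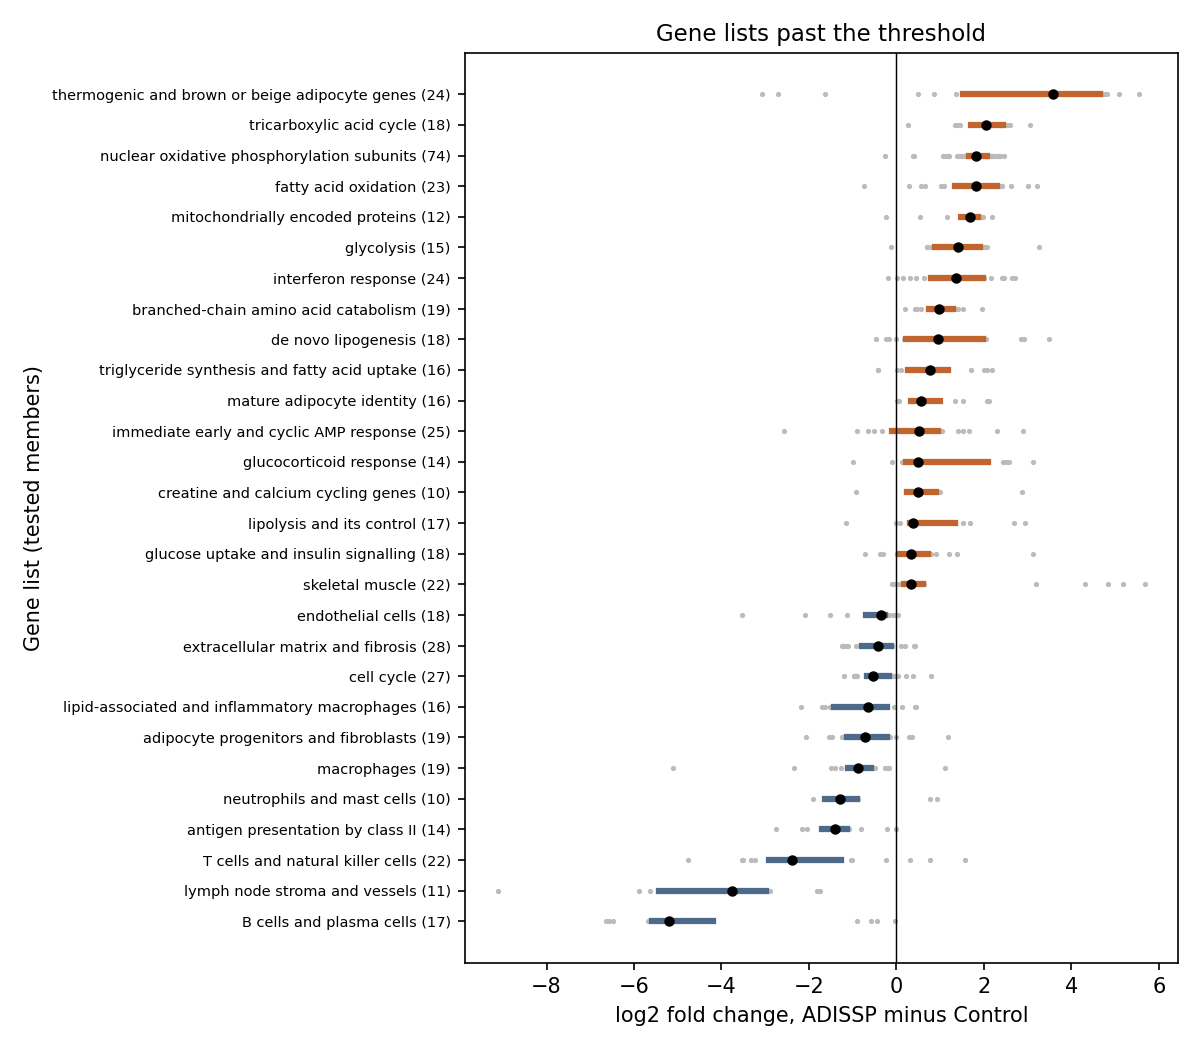
For each of the 28 gene lists past camera's threshold, grey dots are member genes, the bar spans the quartiles (orange higher, blue lower in ADISSP) and the black dot is the median log2 fold change, ADISSP minus Control. Respiratory and thermogenic lists lie to the right (median 3.58 for thermogenic genes) and lymphocyte lists to the left (median -5.20 for B cells). The medians of the lipolysis, glucose uptake, fat cell identity, immediate early and glucocorticoid lists fall below 0 on log2(TPM + 1).

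Most lymphocyte genes fell steeply in ADISSP, together with genes of the lymph node's own stroma and vessels, while Ighm, Igkc and Jchain did not pass. The inguinal fat pad carries a lymph node, and the mean log2 CPM of each of the 4 lists below was highest in Control 1 and 2, lower in Control 3 and lowest in ADISSP. Of 17 B and plasma cell genes 13 fell and 0 rose, the same adjusted over the list alone, with a median of -5.20. The B cell surface gene Ms4a1 went from 45.8 ± 28.5 to 0.487 ± 0.285 CPM (log2 fold change -6.56, SE 0.97, adjusted p = 0.00720). Fcrla fell by 4.19 and Blk by 4.81. The 4 that did not pass, named after their values were seen, were the secretory gene Xbp1 (-0.02) and the immunoglobulin genes Ighm (-0.43), Igkc (-0.89) and Jchain (-0.58). Of these, Ighm passed without ADISSP 1 (-0.70, adjusted p = 0.0228). All 11 lymph node stroma and vessel genes fell, also adjusted over the list alone, with a median of -3.77. Glycam1 had no count in ADISSP and was at least 59.3-fold lower, with 3 counts over the group as the floor. Ccl19 had 3 counts in ADISSP and was 57.2-fold higher in Control, with a 95% exact counting interval of 19.3 to 279. Cxcl13 fell by 3.77. Of 22 T and natural killer cell genes 15 fell and 1 rose, or 17 and 1 adjusted over the list alone, with a median of -2.38. Cd4 fell by 3.54, Zap70 by 2.08 and Cd8a by 3.51, while Gzmb, named after its value was seen, rose (1.58), a call lost without ADISSP 1 (adjusted p = 0.0629). Of 14 class II antigen presentation genes 10 fell (11 adjusted over the list alone) and 0 rose, with a median of -1.39. H2-DMb1 fell by 1.08, H2-DMa by 1.28 and Cd74 by 1.65. Camera's adjusted p was 2.7e-07 for B cells, 5.6e-06 for lymph node stroma, 1.1e-04 for T cells and 1.6e-04 for class II. These lists had adjusted p = 0.441 with an estimated correlation, except T cells (adjusted p = 0.482). With Control 3 as the only control, 13 B cell, 8 stroma, 9 T cell and 6 class II genes were lower past the threshold and 1 T cell gene (Gzmb) was higher, while H2-DMa and Zap70 did not pass.

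**Figure D3:**
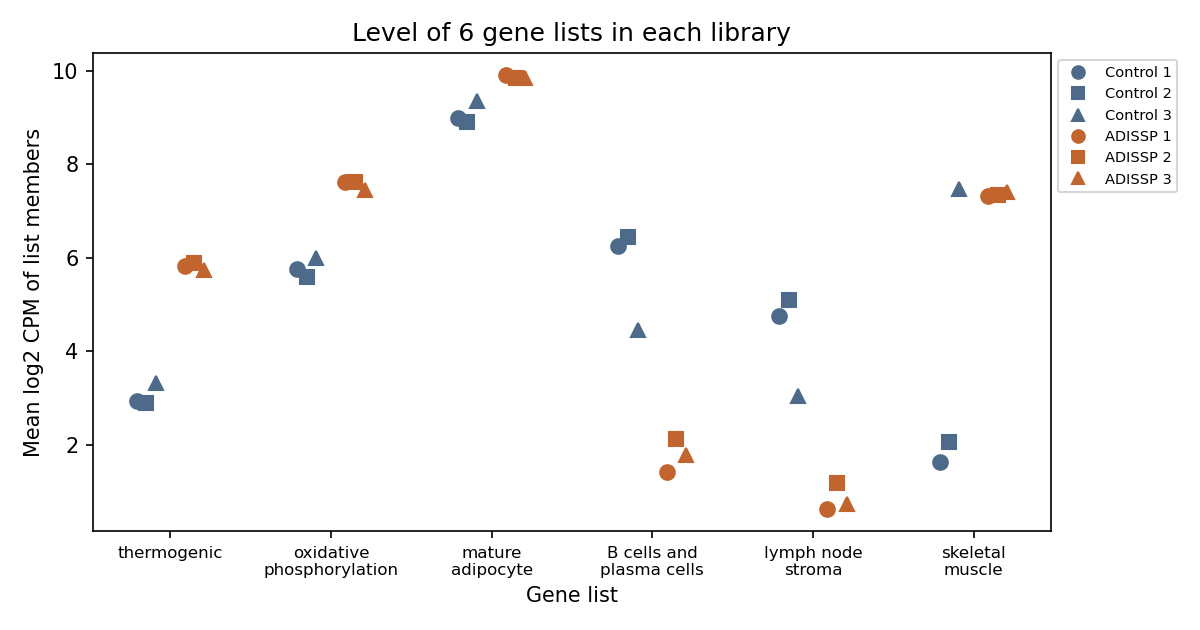
Each point is the mean log2 CPM of a gene list in 1 library, for thermogenic genes, nuclear respiratory chain subunits, fat cell identity, B cells, lymph node stroma and skeletal muscle. Control 3 lies between the groups for B cells (4.46) and with the ADISSP libraries for skeletal muscle (7.46), and thermogenic genes reach 3.33 in Control 3 and 5.75 to 5.89 in ADISSP.

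Genes of tissue macrophages fell, and so did most changed genes of lipid-laden macrophages. Of 19 macrophage genes 14 fell and 1 rose, or 15 and 1 adjusted over the list alone, with a median of -0.87. Adgre1, which encodes the macrophage marker F4/80, went from 45.2 ± 4.90 to 23.2 ± 2.87 CPM (log2 fold change -0.97, SE 0.13, adjusted p = 7.9e-04). The growth factor receptor Csf1r fell by 1.27 and Lyve1 by 2.35, and the 1 that rose, named after its value was seen, was Fcgr1 (1.12). Lyve1 stood at 25.6, 27.5 and 15.4 CPM in Control 1, 2 and 3, lowest in Control 3 as lymphocyte genes were. Of 16 genes of lipid-associated macrophages 9 fell and 2 rose, or 10 and 2 adjusted over the list alone, with a median of -0.66. Ctsk fell by 1.52, Cd9 by 0.82 and Cd63 by 0.46. The 2 that rose, named after their values were seen, were Lipa (0.44) and Plin2 (0.44). On log2(TPM + 1) they were -0.14 and -0.13, and Plin2 lost its call without any 1 library other than Control 3 (adjusted p up to 0.149). Against Control 3 alone 9 macrophage and 9 lipid-associated macrophage genes were lower past the threshold, and Fcgr1, Lipa and Plin2 did not pass. Of 10 neutrophil and mast cell genes 5 fell and 1 rose, or 6 and 1 adjusted over the list alone, with a median of -1.28. The 5 that fell are mast cell genes: Cpa3 (-1.90), Cma1 (-1.64), Mcpt4 (-1.60), Tpsb2 (-1.63) and Kit (-0.91), while the mast cell enzyme Hdc rose (0.76), with Tpsb2, Kit and Hdc named after their values were seen. In Control 1, 2 and 3 Cpa3 stood at 10.8, 10.3 and 5.26 CPM and Mcpt4 at 14.5, 14.5 and 8.07 CPM, lowest in Control 3 as lymphocyte genes were. With the B cell score as a covariate Cpa3, Mcpt4 and Tpsb2 turned to 0.069, 0.42 and 0.55, none past the threshold. Of this list 0 were higher and 1 (Cpa3) lower past the threshold against Control 3 alone. Hdc lost its call without Control 1 or 2 or ADISSP 1 or 2 (adjusted p up to 0.123). The adjusted p of camera was 8.3e-06 for macrophages, 0.00774 for lipid-associated macrophages and 0.0245 for neutrophils and mast cells, each with adjusted p = 0.441 with an estimated correlation. The neutrophil and mast cell list lost its call with no filter on low counts (adjusted p = 0.115), with the stricter filter (0.0646), on library totals (0.208) and without Control 1 (adjusted p = 0.0795), Control 2 (0.0681) or ADISSP 3 (0.138).

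Inflammatory signals gave no single direction. The cytokine Tnf was low and went from 3.07 ± 1.66 to 0.885 ± 0.291 CPM (log2 fold change -1.81, SE 0.52, adjusted p = 0.0267). Control 1, 2 and 3 held 3.86, 4.19 and 1.16 CPM of Tnf, lowest in Control 3 as for lymphocyte genes. With the B cell score as a covariate the value was 2.22 and did not pass. Tnf lost its call without any 1 library other than Control 3: -1.62 (adjusted p = 0.0868) and -1.52 (0.0920) without Control 1 and 2, and -1.54 (0.0964), -1.96 (0.0648) and -1.91 (0.0732) without ADISSP 1, 2 and 3. The chemokine Ccl2 went from 4.16 ± 0.540 to 6.77 ± 3.49 CPM (log2 fold change 0.71, SE 0.37, adjusted p = 0.163), which did not pass, and passed without ADISSP 2 (1.04, adjusted p = 0.0299). Of 24 cytokine, chemokine and acute phase genes 6 fell and 2 rose, or 8 and 2 adjusted over the list alone. The median was -0.04 and camera's adjusted p 0.382, with a median of 0.03 without ADISSP 2 and 0.02 without ADISSP 3. Cxcl12 fell by 0.65, Cxcl14 by 1.36 and Ccl11 by 0.66. The 2 that rose, named after their values were seen, were Cxcl9 (0.90) and Lcn2 (2.57), and Lcn2 lost its call without Control 1 (adjusted p = 0.0563). Of 24 interferon response genes 10 rose (11 adjusted over the list alone) and 0 fell, with a median of 1.36. Irf7, a transcription factor of that response, went from 20.3 ± 0.575 to 108 ± 21.8 CPM (log2 fold change 2.41, SE 0.15, adjusted p = 1.4e-05). Bst2 rose by 1.90 and Gbp3 by 1.61. Camera's adjusted p for interferon genes was 5.6e-05, and adjusted p = 0.461 with an estimated correlation. The median was 0.79 without ADISSP 1, whose mean of this list was 5.96 against 5.05 and 4.71 in ADISSP 2 and 3, and 5 genes were higher past the threshold against Control 3 alone.

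Of the genes of connective tissue, of the cells that form fat cells and of endothelium, nearly all that changed were lower in ADISSP. Of 28 extracellular matrix genes 13 fell and 1 rose, or 15 and 1 adjusted over the list alone, with a median of -0.42. The collagen gene Col1a1 went from 848 ± 71.5 to 587 ± 82.5 CPM (log2 fold change -0.53, SE 0.14, adjusted p = 0.0165). It lost its call without Control 1 (-0.54, adjusted p = 0.0510), ADISSP 1 (-0.41, 0.0753) or ADISSP 2 (-0.55, 0.0593). Col6a3 fell by 1.21, Col3a1 by 1.14 and Loxl2 by 1.23. The 1 that rose, named after its value was seen, was Loxl1 (0.40), which was -0.18 on log2(TPM + 1). Of 19 progenitor and fibroblast genes 9 fell, the same adjusted over the list alone, and 0 rose, with a median of -0.72 that was -0.37 without ADISSP 1. Lum fell by 2.06, Dcn by 1.53 and Pdgfra by 1.18. Of 18 endothelial genes 8 fell, the same adjusted over the list alone, and 0 rose, with a median of -0.36. Plvap fell by 2.09, Vwf by 1.14 and the lymphatic regulator Prox1 by 3.53. Prox1 stood at 6.69, 8.32 and 2.26 CPM in Control 1, 2 and 3, lowest in Control 3 as lymphocyte genes were. With the B cell score as a covariate it was 0.19 and did not pass. Camera's adjusted p was 1.8e-04 for matrix, 0.00179 for progenitors and 2.5e-04 for endothelium, each with adjusted p = 0.441 with an estimated correlation. With Control 3 as the only control, 15 matrix, 8 progenitor and 7 endothelial genes were lower past the threshold, and Loxl1 did not pass. Smooth muscle and pericyte genes did not shift as a list (median -0.08, camera adjusted p 0.454), and its median was 0.08 without ADISSP 2. The 2 of 14 that fell (1 adjusted over the list alone), named after their values were seen, were Pdgfrb (-0.44) and Abcc9 (-0.35), with Abcc9 not past the threshold without Control 1 or 2 or ADISSP 1 or 2 (adjusted p up to 0.162).

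Skeletal muscle genes varied strongly within Control, and a few of them, mostly of slow and oxidative fibres, rose in ADISSP. Of 22 skeletal muscle genes 5 rose and 0 fell, the same adjusted over the list alone. The slow myosin Myh7 went from 0.703 ± 0.364 to 25.7 ± 8.19 CPM (log2 fold change 5.18, SE 0.43, adjusted p = 1.6e-04). The fast oxidative myosin Myh2 went from 1.13 ± 0.281 to 57.9 ± 39.5 CPM (5.69, adjusted p = 0.00755), a call lost without Control 1 (5.66, 0.0501) or Control 2 (5.53, 0.0505). Tnnt1 rose by 3.20, and the other two, the fast myosin Myh1 (4.85) and myoglobin, Mb (4.32), were named after their values were seen. Summed over 8 fast fibre genes, Myh1 included, a list written after the main results were seen, the libraries held 24.5, 37.6 and 8927 CPM in Control and 3183, 3725 and 3742 CPM in ADISSP. Summed over 8 slow and oxidative fibre genes, written at the same time, they held 2.89, 3.75 and 5.81 CPM and 172, 75.3 and 117 CPM. The list's median was 0.34 and its mean 1.24, with a camera adjusted p of 2.5e-04 and direction up, and adjusted p = 0.492 with an estimated correlation. The median was -0.25 without Control 1, -0.25 without Control 2 and 5.86 without Control 3. With all libraries it was 0.09 on library totals and 2.77 on log2(TPM + 1). In the comparison with Control 3 alone 3 were higher and 16 lower past the threshold, with a median of -1.24, and Myh2 (5.34) and Myh1 (3.90) stayed higher without passing.

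The cell division genes that changed fell, and most of the changed genes that answer glucocorticoids and acute stimulation rose. Of 27 cell cycle genes 8 fell, the same adjusted over the list alone, and 0 rose, with a median of -0.53. Mcm3 fell by 0.96, Top2a by 0.91 and Mcm6 by 0.96. Of 14 glucocorticoid response genes 7 rose and 0 fell, or 8 and 1 adjusted over the list alone, with a median of 0.49 that was -0.07 on log2(TPM + 1). Pdk4 rose by 3.13, Cdkn1a by 1.08 and Mt1 by 2.44. Of 25 immediate early genes 12 rose and 4 fell, or 13 and 5 adjusted over the list alone, with a median of 0.51 that was -0.07 on log2(TPM + 1). Pde4d rose by 1.52, Ier3 by 2.29 and Junb by 0.94, while Egr3 (-2.57), Egr2 (-0.91), Pde4b (-0.64) and Btg2 (-0.51), named after their values were seen, fell. Calls among the genes above were lost for Mcm6 without any 1 library other than Control 3 (adjusted p up to 0.0647), Egr2 without Control 2 or ADISSP 2 or 3 (adjusted p up to 0.0765), and Btg2 without Control 1 or 2 or ADISSP 1 or 2 (adjusted p up to 0.131). The adjusted p of camera was 0.00184 for the cell cycle, 0.00525 for glucocorticoid response and 0.0367 for immediate early genes. With an estimated correlation these were adjusted p = 0.441, 0.499 and 0.445. The immediate early list lost its call without Control 2 (adjusted p = 0.0537) and with the stricter filter (0.0902), and against Control 3 alone none of these 3 lists passed in camera, with 0 cell cycle genes lower, 3 glucocorticoid genes higher and 1 lower (Fam107a, -1.60), and 8 immediate early genes higher and 1 lower (Klf6, -0.49), with Fam107a and Klf6 named after their values were seen. With all libraries neither passed, and Fam107a (-0.98) passed without Control 2 (-1.24, adjusted p = 0.0412). Top2a stood at 20.7, 20.9 and 12.9 CPM and Mcm6 at 19.7, 24.5 and 12.1 CPM in Control 1, 2 and 3, lowest in Control 3 as lymphocyte genes were. With the B cell score as a covariate they were 0.51 and 0.75, neither past the threshold. Camera against Control 3 alone also passed none of the glucose uptake, creatine and calcium, and neutrophil and mast cell lists.

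The remaining lists did not shift in camera, whose adjusted p stands in brackets after each list's median. Circadian clock genes had a median of 0.31 (0.0963), which was -0.02 on library totals and -0.18 on log2(TPM + 1), and the list passed with no filter on low counts (adjusted p = 0.0154) and without Control 3 (median 0.57, adjusted p = 0.0162). In it Nfil3 (1.99), Hlf (1.30) and Bhlhe40 (1.00) rose and Nr1d2 (-0.37) fell. Endoplasmic reticulum stress genes had a median of 0.03 (0.341), which was -0.04 with upper-quartile factors, -0.31 on library totals, -0.42 on log2(TPM + 1) and -0.02 without Control 1. In it Asns (1.21), Sesn2 (0.69) and Hyou1 (0.57) rose (2 adjusted over the list alone). Cholesterol synthesis genes had a median of -0.08 (0.455), or 0.01 without ADISSP 3, with Fdft1 (0.61) and Dhcr7 (0.38) higher and Stard4 (-0.82), Msmo1 (-0.62) and Sc5d (-0.35) lower. Of these 1 rose and 3 fell adjusted over the list alone. Cytosolic ribosomal proteins had a median of -0.11 (0.455, and past the threshold on library totals, 0.0443, with a median of -0.47), with Rps2 (0.57), Rplp2 (0.41), Rpl28 (0.39) and Rpl38 (0.30) higher and Rps4x (-0.54), Rpl12 (-0.44), Rpl5 (-0.42) and Rpl7 (-0.36) lower, or 3 and 1 of 51 adjusted over the list alone. Long nuclear and structural RNAs had a median of 0.11 (0.651), or -0.24 on library totals, with Rpph1 (1.37), Neat1 (0.50) and Rn7sk (0.39) higher and Gas5 (-0.48) lower (3 and 2 adjusted over the list alone). Nerve genes had a median of -0.14 but a mean of 0.13, and camera's direction was up (0.962). In it S100b (3.36, from 8.04 ± 3.85 to 82.2 ± 4.28 CPM) and Erbb3 (0.80) rose and Cnp (-0.85) fell, the same adjusted over the list alone. None of the 6 red blood cell genes passed, over all genes or adjusted over the list alone, with a median of -0.14 (0.483). Only 4 of 23 mammary and skin genes had enough counts, none passed, and their median was 0.21, or -0.13 on library totals. The single genes of these lists were named after their values were seen. On log2(TPM + 1) the sign turned for Hyou1, Dhcr7, Rps2, Rplp2, Rpl28, Rpl38, Neat1 and Rn7sk. With 1 library left out, calls were lost for Bhlhe40, Nr1d2 and Sesn2 without Control 2 or ADISSP 1, 2 or 3 (highest adjusted p 0.103 to 0.141), Dhcr7 without Control 1 or 2 or ADISSP 1 or 2 (adjusted p up to 0.153), Msmo1 without Control 1 or ADISSP 2 or 3 (adjusted p up to 0.110), and Sc5d without Control 1 or ADISSP 1, 2 or 3 (adjusted p up to 0.151). They were also lost for Rpl28 without Control 1 or ADISSP 2 (adjusted p up to 0.0769), Rpl38 without Control 1 or ADISSP 1, 2 or 3 (adjusted p up to 0.121), Rps4x without Control 1 or ADISSP 1 or 3 (adjusted p up to 0.0605), Rpl12, Rpl5, Rpl7, Neat1, Rn7sk and Cnp without any 1 library other than Control 3 (highest adjusted p 0.0861 to 0.132), Rpph1 without Control 1 or 2 or ADISSP 2 (adjusted p up to 0.0736), and Gas5 without Control 1 or 2 or ADISSP 1 or 2 (adjusted p up to 0.104).

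The genes that changed most in either direction lay partly in the groups above and partly outside them. Sgk2, a kinase gene with no count in Control, was at least 40.9-fold higher in ADISSP. Mab21l2 had 1 count in Control and was 137-fold higher in ADISSP (95% exact counting interval 24.0 to 5462). The long non-coding RNA Lncbate10 rose by 5.58, Fam131c by 5.35 and the receptor gene Lgr6 by 5.30 (from 3.65 to 142 CPM). At the other end Pcdh15 and Or13a27 had no count in ADISSP and were at least 115-fold and 34.3-fold lower. Igkj3, an immunoglobulin joining segment whose short length makes its count uncertain, was at least 31.7-fold lower. The B cell genes Cr2 and Fcer2a fell by 6.64 and 6.47. Grem1, a secreted inhibitor of bone morphogenetic proteins, had 1 count in ADISSP and was 130.4-fold higher in Control (95% exact counting interval 23.1 to 5178). In Control 1, 2 and 3 Pcdh15 stood at 10.7, 14.3 and 2.67 CPM and Or13a27 at 3.57, 3.97 and 0.683 CPM. Grem1 stood at 4.48, 5.23 and 0.683 CPM, so all of these were lowest in Control 3 as lymphocyte genes were. Calls were lost for Pcdh15 and Or13a27 without Control 1 (highest adjusted p 0.0516 to 0.0843), and Cr2 and Grem1 without ADISSP 1 (highest adjusted p 0.0545 to 0.0566). The smallest p values belonged to genes that rose evenly in the ADISSP libraries: Pank1 (4.15), Elovl6 (3.48), Cyp2b10 (4.65), Cpn2 (4.92), Kng2 (4.77) and Acot11 (4.77), each with an adjusted p of 1.4e-06. Pank1, a kinase of coenzyme A synthesis, went from 14.4 ± 1.15 to 256 ± 28.0 CPM.

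The balance of higher and lower genes depends on how libraries are scaled. With TMM factors 52.8% of the changed genes were higher. On library totals without factors the median of all genes moved by -0.35 and 1756 genes were higher against 6600 lower (21.0% higher). On log2(TPM + 1) it moved by -0.50, with 1284 higher and 9520 lower (11.9% higher). With upper-quartile factors the median of all genes was -0.09 and 2734 genes were higher against 3506 lower. Thermogenic, respiratory, lymphocyte, macrophage and matrix lists kept their direction under each of these scalings.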

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

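The comparison with Control 3 alone, the fits with a muscle or B cell score and the library totals were chosen after the results were seen. The number of changed genes stayed within 1.5 times of 6058 with RLE factors (6027), upper-quartile factors (6240), no filter (6605, with 19 lists higher, adipokines and circadian clock added), the stricter filter (5250), DESeq2 (6054) and limma-voom (5576). Over 3004 values of 189 named genes under alternatives set beforehand, 2715 kept their direction and side of the threshold, 220 lost their call, 28 gained one and 41 changed sign. Of the named genes, 123 neither lost a call nor changed sign under any of them. DESeq2 gave no adjusted p for 87 genes that edgeR tested. A minimum log2 fold of 1 left 2730 genes (1324 higher, 1406 lower). With 1 library left out, 3823 to 8517 genes changed, 2260 to 4305 higher and 1563 to 4212 lower, with 15 to 18 lists higher and 10 to 11 lower and a thermogenic median of 3.44 to 3.65. The ends 3823 and 1563 came without Control 1, and 8517 and 4212 without Control 3, which differs from the other controls in muscle and lymphocyte genes. With a correlation estimated per list, camera called 0 lists higher and 0 lower, and the thermogenic median of 3.58 had an adjusted p of 0.441. By library totals 1756 genes were higher and 6600 lower. Limma on log2(TPM + 1) called 10804 genes (1284 higher, 9520 lower), on log2(TPM + 0.1) 10736 (1274 and 9462) and unfiltered 11004 (1298 and 9706), and its shift of the median of all genes was -0.50. Against Control 3 alone 3190 genes changed (1886 higher, 1304 lower), with the spread taken from the ADISSP libraries alone. With the muscle score as a covariate 3688 changed (2068 and 1620), and with the B cell score, which itself differs between groups, 267 (153 and 114), with 10 lists higher.

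Signs that turned are given as log2 values, and beyond those constructions the cause was not tested. None of the values that turned with the B cell score passed the threshold. On log2(TPM + 1), with or without the filter, they were Adipoq -0.22, Ccl2 -0.0037, Loxl1 -0.18, Lipa -0.14, Plin2 -0.13, Hyou1 -0.0029, Dhcr7 -0.18, Rps2 -0.017, Rplp2 -0.17, Rpl28 -0.20, Rpl38 -0.27, Neat1 -0.067 and Rn7sk -0.19. On log2(TPM + 0.1) they were Adipoq -0.22, Ccl2 -0.014, Loxl1 -0.18, Lipa -0.14, Plin2 -0.13, Hyou1 -0.0030, Dhcr7 -0.19, Rps2 -0.017, Rplp2 -0.17, Rpl28 -0.20, Rpl38 -0.27, Neat1 -0.067 and Rn7sk -0.19. With the B cell score they were Adipoq -0.47, Tnf 2.22, Ccl2 -0.26, H2-DMa 0.67, Cd74 0.60, Cd4 0.55, Zap70 1.28, Cd8a 0.55, Fcrla 0.91, Cxcl13 1.01, Prox1 0.19, Top2a 0.51, Mcm6 0.75, Epsti1 1.34, Tmem26 1.41, Tnfrsf9 1.24, Igkc 2.33, Jchain 3.05, Plin2 -0.39, Mb -0.092, Lcn2 -1.05, Cpa3 0.069, Mcpt4 0.42, Tpsb2 0.55, Cnp 1.02, Sesn2 -0.26, Bhlhe40 -0.38, Egr3 1.10, Btg2 0.20, Fdft1 -0.084, Rps4x 0.37, Rpl5 0.39, Rpl7 0.22, Rpl12 0.48, Neat1 -0.17, Gas5 0.31, Sp100 0.90, Cd40 1.29 and Pfkm -5.06. Against Control 3 alone they were Igkc 0.24, Jchain 0.68 and Pfkm -0.68, with the muscle score Igkc 0.20, Jchain 0.66 and Pfkm -0.60, and on library totals Rpl38 -0.051. With 1 library left out Xbp1, which passed in none of these fits, ranged from -0.074 to 0.029, with values above 0 without Control 3 or ADISSP 1. 

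With the replicate number as a block, edgeR called 5541 genes (2947 higher, 2594 lower), with 17 lists higher, 11 lower and a thermogenic median of 3.60. Whether the numbers pair the libraries cannot be told from these values. Same-numbered libraries deviated from their group means with correlations of 0.035, 0.080 and 0.050 over genes, each under 0.1. Each library correlated best with its own number, and the other pairs had correlations of -0.059 to 0.016.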

Other observations

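Every test in this part was chosen after the result it concerns was seen, except the counts over other splits of the libraries and the test for classical brown fat, which was written after the rise of brown fat genes was seen but before the values of its markers other than Zic1 and Lhx8. Some of the genes that mark where on the body a fat depot lies differed between the groups. The single genes named here were picked from their sets after their values were seen. The classical brown fat markers Zic1 (4.68, from 0.256 ± 0.257 to 6.48 ± 0.866 CPM), Oplah (2.08), Fbxo31 (1.92) and Ebf3 (0.81) rose, while Epsti1 fell (-2.23) and lost its call without any 1 library other than Control 3 (adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment up to 0.0837). Epsti1 was lower in Control 3 than in Control 1 and 2 (log2 ratio -1.73), as B cell genes were. With the B cell score as a covariate it was 1.34 and did not pass. On log2(TPM + 1) Ebf3 (0.23) did not pass. The anterior Hox genes Hoxa4 (2.37), Hoxa5 (1.34), Hoxc4 (1.11) and Hoxc5 (0.71) rose, 4 of 13 tested (median 0.07), the last not on log2(TPM + 1), and of 6 posterior ones tested only Hoxb9 fell (-3.37, median of the set -0.44). With only Control 3 as control Hoxb9 was -3.33 and did not pass. Of 8 beige and inguinal markers tested, Slc27a1 rose (0.80) and Tbx1 (-3.07), Tmem26 (-2.70), Cd40 (-1.89), Tnfrsf9 (-1.63) and Sp100 (-0.86) fell, with a median of -1.24, or -0.48 against Control 3 alone. Of these, Tmem26, Cd40, Tnfrsf9 and Sp100 were lower in Control 3 than in Control 1 and 2 (log2 ratios -1.83, -1.62, -1.09 and -0.96), as B cell genes were (median -2.24). Calls among these were lost for Cd40 without Control 1 or ADISSP 1, 2 or 3 (adjusted p up to 0.0713), and Tnfrsf9 and Sp100 without any 1 library other than Control 3 (highest adjusted p 0.143 to 0.147). The slow fibre gene Myl2 rose by 4.27. S100b, listed as a Schwann cell gene, went from 8.04 ± 3.85 to 82.2 ± 4.28 CPM, while the median of its list was -0.14.

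The rise of brown fat genes could come from the makeup of the tissue, but fewer lymph node cells in ADISSP would raise fat genes of every kind alike, and the thermogenic median exceeded the fat cell identity median by 3.01 (quartiles 1.52 to 4.65 against 0.35 to 0.99). With the muscle score as a covariate the thermogenic median was 3.29 (quartiles 1.22 to 4.0). That score was 7.46 in Control 3 and 7.32 to 7.40 in ADISSP. It was 1.62 and 2.07 in Control 1 and 2, so this fit leans on Control 3. The fit cannot speak to slow and oxidative muscle, whose genes were higher in ADISSP than in Control 3, so more muscle of that kind stays open. With the B cell score, which did not overlap between the groups, the thermogenic median was 2.39. Tissue taken wholly from an anterior brown depot would lack posterior Hox transcripts, but their summed level had a log2 ratio of -0.39 (74.0, 52.1 and 80.6 CPM in Control and 53.3, 53.3 and 51.2 CPM in ADISSP). A part of classical brown fat in ADISSP is consistent with the median of 1.36 over 8 classical brown markers (4 rose with Zic1 among them, 1 fell, 0.81 against Control 3 alone), a median that was the same without Zic1 and Lhx8, and with summed anterior Hox CPM at a log2 ratio of 0.57, but 4 of 13 anterior genes rose with a median of 0.07 and all 8 markers also had counts in Control, while Zic1 and Lhx8 also stand in the thermogenic list. Among the classical brown markers, Zic1 had a Control mean no larger than its SD and near 1 library's floor, so its counts there say little. Oplah at 307 CPM was the most abundant of these markers in ADISSP, where Ucp1 reached 3075 CPM, and an effect of the treatment on the fat cells themselves stays open, untested.

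The fall of lymphocyte genes may reflect lymph node tissue in the Control libraries. Genes of lymph node stroma that lymphocytes do not make, all 5 of them also in the lymph node list, fell with a median of -5.77 over the 4 with enough counts. The median was -5.74 with Glycam1 set to the ADISSP floor over its mean Control CPM. Summed, these genes went from 69.5, 100.4 and 20.6 CPM in Control to 1.51, 2.21 and 1.28 CPM in ADISSP, with Ccl21a the most abundant. From Control 1 and 2 to Control 3 they fell with a median of -1.85, close to the -2.24 of B cell genes. A loss of lymphocytes and immunoglobulin-secreting cells alike is argued against, since the plasma cell gene Jchain and all tested immunoglobulin genes, 76 in all, of which 23 fell and 0 rose, lay 4.46 above B cell genes in their median (quartiles -2.20 to -0.56 against -5.87 to -5.10), summing to 1898, 2089 and 1182 CPM in Control and 1280.3, 1190.0 and 727 CPM in ADISSP. From Control 1 and 2 to Control 3 the plasma cell and immunoglobulin genes fell with a median of -1.77, near those of stroma and B cell genes. Between the controls these sets thus fell alike. Against Control 3 alone the median was 0.24 for plasma cell and immunoglobulin genes and -3.73 for mature B cell genes. Whether the node was dissected away differently or the treatment changed it was not tested.

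Skeletal muscle genes differed between the libraries in amount and in kind. Muscle of 1 composition in different amounts would keep the ratio of fibre types, but against Control 3, the control with muscle genes, slow and oxidative fibre genes lay 5.53 above fast fibre genes, Myh1 among the fast (medians 4.2 and -1.34). The most abundant of the 2 sets were Myh4 at 4932 CPM in Control 3 and Myh2 at 57.9 CPM in ADISSP, and Myh7, Myh2, Tnnt1 and Mb of the slow and oxidative set also stand in the muscle list. The rise of Myh7, Myh2, Tnnt1 and Mb was seen before that set was written, so the gap of 5.53 is in part built in. Muscle of another kind or place, and expression of these genes by other cells, stay open.

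Splitting the 6 libraries into 3 and 3 gives 10 splits, so the share with a result as large cannot go below 0.1. The real split gave 6058 changed genes (3197 higher, 2861 lower), 1 of the 10 splits with as many in each count, and the highest of the others was 0 in edgeR, where 61 to 1042 genes had an unadjusted p under 0.05. Each of the other splits holds libraries of both groups on either side, so the difference between the groups adds to its spread. Their count of 0 is therefore no measure of what chance gives. For lists, 17 were higher in the real split and 20 in the highest other, so that 3 splits gave as many. It gave 11 lists lower against 9, and a thermogenic median of 3.58 against 1.01, each in 1 split.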
